A study of Mus musculus with 6 samples.

How the data were processed

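Total RNA from pooled urogenital ridges was labelled with biotin and hybridised to single-colour Amersham CodeLink Mouse 20k arrays, per the labels' protocols and the series description. The deposited values are spot intensities on a linear scale, 1 column per array, in which the median of every column lies between 0.956 and 0.966. The software, the background correction and the flagging the authors used are not given in the sources used here. The deposited intensities include 153 to 246 values at or below 0 per array and 190 to 212 empty cells per array, and they carry no detection flags, so a dim signal cannot be told from background by a flag. No normalization beyond that in the deposited values was applied for the main results, because the medians of the log2 values differed by only 0.0153 between arrays, under the limit of 0.1 set before the data were examined. All rules, tests, gene lists and alternatives were likewise set before the data were examined, unless stated otherwise.

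Values under the 5th percentile of all positive values, an intensity of 0.0811, were set to that floor and log2 was taken. A probe was tested if at least 2 arrays of each genotype had a value and its mean log2 over the 6 arrays lay above the 25th percentile of probe means, which corresponds to an intensity of 0.217. This left 15062 of 20289 probes. Control features could not be recognised from the table, in which probes carry numbers only, and none was left out on that ground. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend in the variance prior), 3 arrays against 3 with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes (two-sided). Every adjusted p of a gene comes from this fit, unless another setting is named beside it. Folds are 2 to the power of the log2 change, and means ± SD are of the intensities before the floor. Where the mean of the lower genotype lay below the 25th percentile limit, the fold is given as a lower bound, the higher genotype's mean over the lower genotype's mean of, per array, the higher of that limit and the probe's own value. These are means of log2 values. This form of the bound was set after the data were examined.

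Probes were named through GEO's platform annotation, which can be old. It gave 1 gene symbol for 15120 probes and several for 38, from which no gene was named, and it did not list 5131. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, in which 56 of the named probes found no match and kept the annotation's symbol. No coordinates are given, because the probes' build is not stated. Of the symbols in the lists, 17 were older names replaced by current ones.

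Lists of genes, 27 in all, were fixed for the cell types of the ridge and its neighbours, for pathways and for checks of dissection level and sex. Each list gene was represented by its brightest probe with values on all arrays. Probes of 1 gene disagreed for some list members: for Nr2f2, Igf1r and Maf a dimmer probe passed the threshold as lower while the brighter probe used in the lists did not pass, and for Col5a1 a dimmer probe passed as higher. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 27 lists. None of the 13 lists called held in camera with a correlation estimated from the arrays, where the smallest adjusted p was 0.111 and 5 lists had an unadjusted p under 0.05. The estimate was above 0.01 for some called lists, such as the endothelial one (0.193). For others it was below 0.01, as for the neural crest (-0.020), gonadal primordium (-0.043) and muscle (-0.027) lists. A correlation higher than the preset one thus does not account for the lost calls of these 3 lists. The self-contained test fry called 19 lists. It tests whether a list's genes move on balance one way and does not compare them with other genes.

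The genes named are Wt1, the 12 largest increases and 12 largest decreases, up to 4 genes of each list and all tested genes of the sex chromosome list. The increases and decreases were ranked among genes with 1 symbol that is not a placeholder, adjusted p under 0.05, a change of at least 2-fold, no overlap between genotypes and a mean in the higher genotype above the median probe, which 124 higher and 282 lower genes met. From a list, the genes past the threshold with the largest change were taken, or the brightest ones where fewer than 2 passed. The fit was tested on simulated arrays with the real means and spreads of 15019 probes, 200 of them changed. It recovered 32.8% of changes of 0.5 on the log2 scale, 77.6% of changes of 1 and 89.4% of changes of 2, with 6 false calls. In the data 41.3% of the tested probes were called, a far larger share than was changed here. Adjusted p-values depend on that share, so these rates and false calls do not carry over to the real fit. At the preset correlation, camera called a simulated list shift of 0.5 and no other list. It also called the shifted list with an estimated correlation (adjusted p = 0.0220). The simulated probes were drawn independently of each other. The simulation therefore does not show how often camera makes false list calls where genes are correlated.

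The alternatives tried were quantile and cyclic loess normalization, no filter and a stricter filter on dim probes, no floor, a floor at the 20th percentile, a pseudocount at the 10th percentile, no trend in the variance prior, array weights, complete probes only, the replicate number as a block, each array left out in turn, no variance moderation other list tests and the mean of all probes of a gene. Counts of list members under the other normalizations and without knockout array 1, and 2 lists without Amhr2, were added after seeing the data. The figures were drawn with matplotlib 3.10.9.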

Results

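Gene expression was measured in the urogenital ridge of mouse embryos at E11.5, just before the sexes diverge. The ridge is the embryonic tissue that holds the coelomic epithelium, the gonadal primordium and the mesonephros, the transient embryonic kidney. The comparison asked which transcripts depend on Wt1, the Wilms tumour gene, which encodes a zinc finger transcription factor. Wild-type Mf1 embryos were compared with embryos homozygous for a Wt1 deletion, with 3 single-colour oligonucleotide arrays per genotype and 6 in all. Every array was labelled as a pool of 5 embryos, 4 female and 1 male, with 11 to 12 tail somites. The labels do not say that the 3 arrays of a genotype came from separate pools, so the p-values below measure only the spread between these arrays, which may be technical. The arrays held 20289 probes, of which 20077 to 20099 had a value on any one array. The number of arrays limits the precision. The arrays of 1 genotype correlated with each other at r = 0.991 to 0.992 in wild type and 0.983 to 0.986 in knockout (Pearson's r across probes, which are not independent replicates), and the 9 pairs across genotypes at 0.966 to 0.972. The median SD between the arrays of a genotype was 0.0952 on the log2 scale in wild type and 0.153 in knockout.

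Wt1 itself was lower in the knockout on both of its probes. On the brighter probe (2836), the wild-type arrays had deposited intensities of 44.1, 43.6 and 39.1 and the knockout arrays 14.3, 15.7 and 14.2. The means were 42.3 ± 2.77 and 14.7 ± 0.788 (SD, n = 3 each), a log2 change of -1.52 ± 0.08 (SE) with adjusted p = 1.13e-07, and 34.9% of the wild-type signal remained. On the dimmer probe (17965), the means were 0.855 ± 0.0859 and 0.289 ± 0.167 (SD, n = 3 each), with a log2 change of -1.74 ± 0.37 and adjusted p = 0.00273. The sources used here do not give the position of either probe relative to the deleted part of the gene, so the remaining signal does not measure intact transcript.

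Expression differed widely between the genotypes. The largest change was in Amhr2, the receptor for anti-Müllerian hormone, whose signal was 64.1-fold lower in the knockout (30.6 ± 1.77 against 0.480 ± 0.0575, SD, n = 3 each, adjusted p = 8.85e-12). Kctd14 was 35.8-fold lower, from 127 ± 9.39 to 3.58 ± 0.520 (adjusted p = 2.67e-11). Slc9a3r1, a scaffold that ties membrane proteins to the actin cytoskeleton, was 22.1-fold lower, Cd59a, an inhibitor of complement lysis, 17.5-fold and the receptor-type phosphatase gene Ptprv 15.7-fold. Aldh1a1, a retinaldehyde dehydrogenase, fell from 17.1 ± 0.784 to 2.13 ± 0.174, or 8.02-fold, and Rpp25, a subunit of ribonuclease P, fell 7.52-fold. The knockout signal of 5 further genes lay below the limit used to leave out dim probes, so their folds are lower bounds set against that limit or, on arrays where the probe's own value was higher, against that value. Akr1cl, an aldo-keto reductase gene, was at least 13.3-fold lower, the mesothelial mucin gene Muc16 at least 8.54-fold, and Tulp2 at least 8.36-fold. Cst9, a cystatin gene of Sertoli cells, was at least 5.53-fold lower and Tac2, the neurokinin B precursor, at least 4.60-fold. All of these genes passed the threshold at adjusted p of 7.48e-05 or less in limma's moderated test.

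The 12 largest gains included genes of the nervous system, of skeletal muscle and of hormone-producing cells, among others. Zic1, a transcription factor of the dorsal neural tube and somites, rose 19.5-fold from 1.51 ± 0.112 to 29.5 ± 1.59 (SD, n = 3 each, adjusted p = 2.67e-11). Tnnc2, the troponin C of fast skeletal muscle, rose 19.4-fold from 0.352 ± 0.0916 to 6.68 ± 0.313. The other muscle genes among the 12 largest gains were Mstn, which encodes myostatin, 12.5-fold higher, and Myh3, the embryonic myosin heavy chain gene, 7.27-fold higher. Gcg, the glucagon precursor, was at least 13.3-fold higher, and Pyy, which encodes peptide YY, was 10.6-fold higher (log2 change 3.40 ± 0.08, SE). The homeobox genes Dbx1, of spinal cord progenitors, and Hmx1 were at least 6.44-fold and 5.71-fold higher. Tlx1, a homeobox gene needed for the spleen, rose 6.79-fold, and Dmrt2, a transcription factor gene of the dermomyotome, 6.30-fold. Vtn, which encodes vitronectin, rose 7.44-fold and Ttr, which encodes transthyretin, 6.40-fold. The largest adjusted p among these 12 genes was 8.71e-05 (limma).

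Across the array, 6221 of 15062 tested probes passed adjusted p under 0.05, with 3625 higher and 2596 lower in the knockout. A change of at least 2-fold was called at 706 probes, 236 higher and 470 lower, and a change of at least 4-fold at 29 higher and 49 lower. Without the filter on dim probes, 428 were at least 2-fold higher and 485 lower, so the excess of losses among the 2-fold changes was smaller with dim probes kept. The arrays of the genotypes did not overlap at 52.8% of the tested probes, where chance gives 10%. The median log2 change over all tested probes was 0.09, and it was 0.26 in the brightest eighth of the probes and 0.17 in the dimmest eighth. Quantile normalization took these medians to 0.03, -0.00024 and -0.04 and gave 3043 higher and 2954 lower probes. The direction of small changes in the brightest and the dimmest genes thus depended on the scaling.

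**Figure D1:**
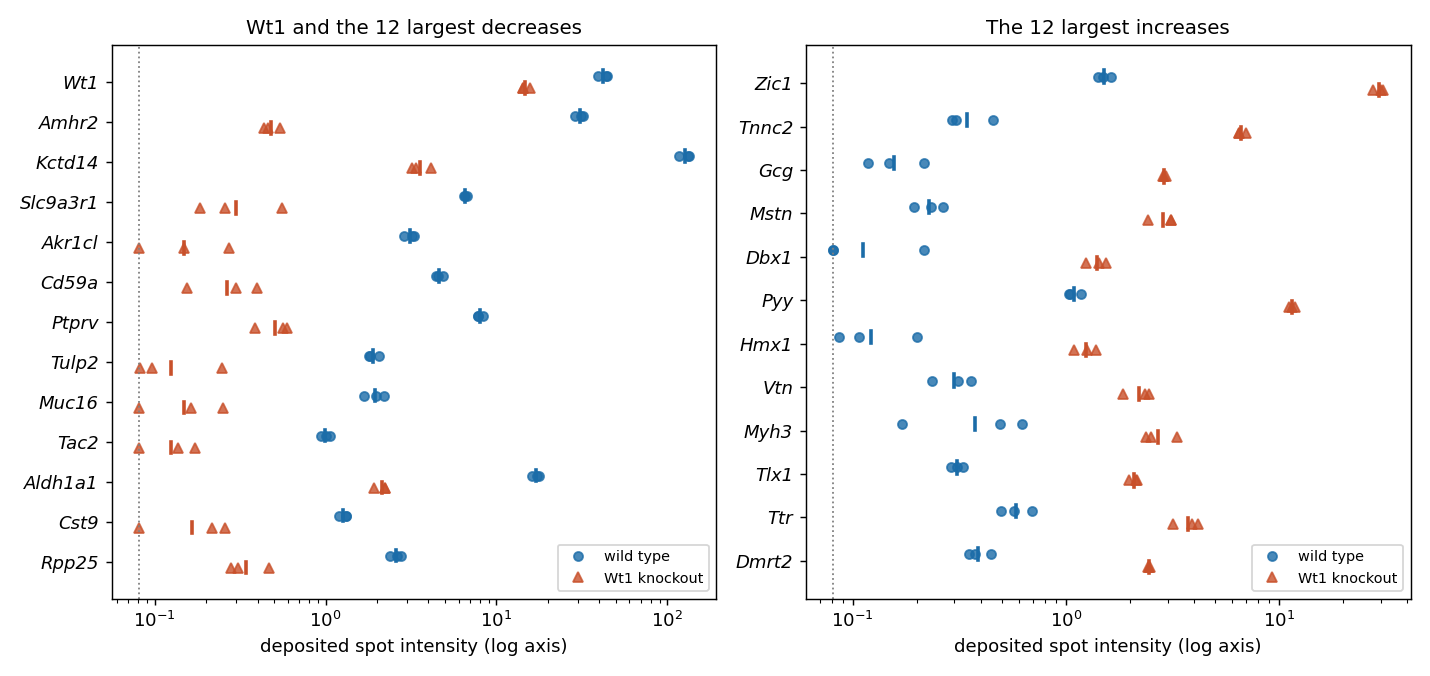
Deposited spot intensity (log axis) on each of the 3 wild-type (circles) and 3 Wt1 knockout arrays (triangles), for Wt1 with the 12 largest decreases (left) and for the 12 largest increases (right). Short bars are means of the log2 values and the dotted line is the floor of 0.0811 at which lower values are drawn; Amhr2 lies 64.1-fold lower and Zic1 19.5-fold higher in the knockout.

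Of 17 tested members of the gonadal primordium list, 9 fell, 3 rose and 5 did not pass. After Amhr2, the largest decreases were in Lhx9, a homeobox gene needed for gonad formation, which fell 3.78-fold from 4.23 ± 0.218 to 1.12 ± 0.0531 (SD, n = 3 each), in Nr0b1, which encodes the nuclear receptor DAX1 and fell 3.52-fold, and in Zfpm2, a cofactor of GATA4, which was at least 2.54-fold lower. The median log2 change of the list was -0.40, with adjusted p = 0.00759 in the camera list test and adjusted p = 0.20 with an estimated correlation. Without Amhr2 the median was -0.23 and the adjusted p was 0.0265, or adjusted p = 0.20 with an estimated correlation. The counts adjusted over the list alone were the same, 9 lower and 3 higher. On the list of genes reported as Wt1 targets in the literature, 12 of 30 members fell and 3 rose, against 13 and 3 when adjusted over the list alone. They included Inha, the inhibin alpha subunit, 3.10-fold lower, and Tgfb1, 2.20-fold lower. That list gave adjusted p = 0.00361, and adjusted p = 0.194 with an estimated correlation. Its entry for Amhr2 may rest on work with these samples and is not independent evidence. Without it the adjusted p was 0.0124, or adjusted p = 0.20 with an estimated correlation.

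Of the 18 genes on the steroidogenic list, 11 were on the array and 7 were tested. Star, Cyp11a1, Cyp17a1, Cyp21a1 and Cyp11b1 were not among those tested, so the list says little on steroidogenic genes as a whole. Of the 7, 4 fell and none rose, with the same counts when adjusted over the list alone. The inhibin subunit gene Inha was 1 of the 4. Hsd3b1 and Hsd3b6, closely related 3-beta-hydroxysteroid dehydrogenase genes whose probes may not separate them, were at least 4.61-fold and 3.76-fold lower, and Scarb1, the HDL receptor that delivers cholesterol, fell 2.42-fold. The 3 members that did not pass were Mc2r, Fdx1 and Mrap, with log2 changes of -0.23, 0.16 and 0.34, named after their values were seen. The list's median log2 change was -1.28, which is the value of Scarb1 (camera, adjusted p = 0.0230, and adjusted p = 0.20 with an estimated correlation). On the coelomic epithelium and mesothelium list, 8 of 15 members fell and 2 rose, against 9 and 2 when adjusted over the list alone. Besides Muc16, Aldh1a1 and Wt1, the members that fell included the keratin gene Krt8, 2.70-fold lower. The 2 that rose were Gata5, 1.29-fold, and Aldh1a2, 1.40-fold, while Krt18, Upk1b, Bnc1, Lrrn4 and Tbx18 did not pass over all probes. The members that rose or did not pass were named after their values were seen. The median of the coelomic list was -0.54 (camera, adjusted p = 0.00759, and adjusted p = 0.20 with an estimated correlation). Wt1 is the deleted gene, so its fall is no independent evidence, and this list was not tested without it. Genes of sex determination went both ways, with 6 of 14 lower and 1 higher, against 7 and 2 when adjusted over the list alone. After Cst9, Vnn1 fell 2.25-fold and Fst, which encodes follistatin, 1.90-fold, while Fgf9, a growth factor gene of the testis pathway, rose 1.68-fold from 1.10 ± 0.0744 to 1.86 ± 0.308. This list's adjusted p was 0.0416, 0.390 with an estimated correlation, and the call ended in 6 settings: under quantile and cyclic loess normalization, without a floor, without a trend in the variance prior, and without knockout array 1 or 3. Over all alternatives with this test the adjusted p ran from 0.0177 to 0.111.

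Of 13 tested germ cell genes, 6 fell and 1 rose. Ifitm1, an interferon-induced membrane protein gene used as an early germ cell marker, fell 3.44-fold from 105 ± 8.01 to 30.4 ± 0.261, and Dazl, an RNA-binding protein gene of germ cells, was at least 2.54-fold lower. Alpl, the alkaline phosphatase that stains primordial germ cells, fell 1.89-fold. The list's median was -0.34 (adjusted p = 0.0230, and adjusted p = 0.20 with an estimated correlation). Of 19 endothelial genes, 6 fell and 1 rose, led by the adhesion molecule gene Pecam1, 2.49-fold lower, and Emcn, 1.76-fold lower (list median -0.19, adjusted p = 0.0265, and adjusted p = 0.518 with an estimated correlation). Of 12 smooth muscle and pericyte genes, 5 fell and none rose. Acta2, smooth muscle actin, went from 58.6 ± 4.48 to 33.6 ± 2.65 (median -0.27, adjusted p = 0.0235, and adjusted p = 0.390 with an estimated correlation). On the mesenchyme and matrix list, 10 of 25 fell and 2 rose. The collagen gene Col1a1 fell 4.24-fold and Tgfbi 4.41-fold, while the somite gene Meox2 rose 4.0-fold (median -0.20, adjusted p = 0.00997, and adjusted p = 0.390 with an estimated correlation). Each of these 4 lists had the same counts when adjusted over the list alone. Without knockout array 1 the endothelial and matrix lists missed the threshold, at adjusted p = 0.0680 and 0.0569, the highest over their alternatives with this test, whose lowest were 0.00998 and 0.00308.

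On the Wnt list, 10 of 21 members fell and 3 rose, with the same counts when adjusted over the list alone. Wnt4, a Wnt ligand of the early gonad and kidney, fell 2.15-fold from 39.8 ± 0.378 to 18.6 ± 1.92, and Tcf7l2, a transcription factor of the pathway, 2.24-fold. The Wnt list gave adjusted p = 0.0416, and adjusted p = 0.331 with an estimated correlation. Its call also ended in 6 settings, under quantile and cyclic loess normalization, without a trend in the variance prior, and without wild-type array 2, knockout array 1 or knockout array 3. Over all alternatives with this test its adjusted p ran from 0.0173 to 0.111. On the BMP, TGF-beta and FGF list, 9 of 26 fell and 3 rose, again with the same counts over the list alone. Id1, a BMP-responsive gene, fell 2.22-fold, the feedback inhibitor gene Spry2 2.0-fold and the receptor gene Fgfr1 1.92-fold. That list had adjusted p = 0.0313, 0.331 with an estimated correlation, and 0.0569 without knockout array 1. Its call also ended under cyclic loess normalization and without a trend in the variance prior, and its adjusted p ran from 0.0154 to 0.0575 over the alternatives with this test.

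Of the 27 lists, 2 passed the camera test as higher at the preset correlation, and neither passed with an estimated one. They are the lists of neural crest and sympathetic neurons and of skeletal and cardiac muscle. Of 19 neural crest and neuronal genes, 15 rose and none fell, adjusted over all probes or over the list alone. The neuronal tubulin gene Tubb3 rose 3.32-fold from 2.25 ± 0.176 to 7.52 ± 1.14, Dcx, which encodes doublecortin, 3.32-fold on its brighter probe (a dim second probe had a log2 change of -0.03 ± 0.52, SE), the neuronal RNA-binding protein gene Elavl3 2.73-fold and Stmn2 2.60-fold. The median log2 change was 0.79 (adjusted p = 1.52e-06, and adjusted p = 0.111 with an estimated correlation). Of 16 muscle genes, 9 rose and 2 fell, against 11 and 2 when adjusted over the list alone. After Tnnc2 and Myh3, the largest gains were in the cardiac homeobox gene Nkx2-5, at least 3.01-fold higher, and in Myf5, a myogenic determination gene, 5.02-fold higher, whereas Des, which encodes desmin, fell 1.80-fold. The other member that fell, the atrial myosin light chain gene Myl7, had a log2 change of -1.05 ± 0.09 (SE) and was chosen after its values were seen. The median was 1.21 (adjusted p = 0.0285, and adjusted p = 0.20 with an estimated correlation), and the call ended without knockout array 1 (adjusted p = 0.0610), among probes above the median probe (adjusted p = 0.463) and without a trend in the variance prior, with 0.0168 as the lowest over the alternatives with this test. The same arrays that showed the lower gonadal, steroidogenic and coelomic genes showed these higher muscle and neuronal genes, with list medians of -0.40, -1.28 and -0.54 against 1.21 and 0.79. The steroidogenic median rests on only 7 genes, of which 3 did not pass.

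**Figure D2:**
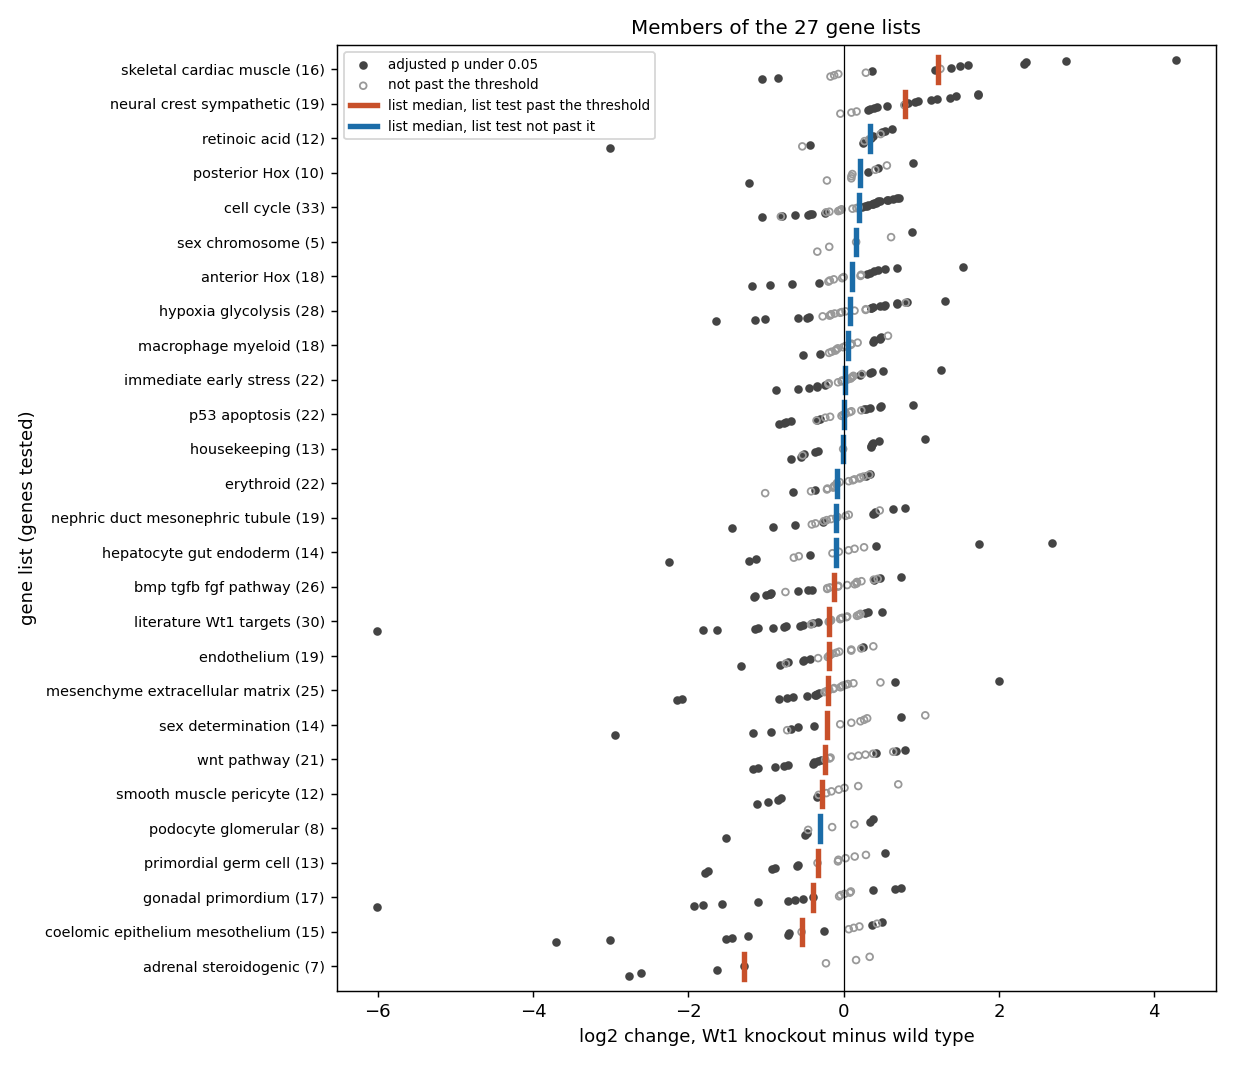
Log2 change between Wt1 knockout and wild type for each tested member of the 27 gene lists, ordered by list median, with filled points for members at adjusted p under 0.05 and a bar at the median, red where the list test passed the threshold. The muscle and neural crest lists have the highest medians, 1.21 and 0.79, and the steroidogenic list the lowest, -1.28.

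The remaining 14 lists did not pass the list test. On the nephric duct and tubule list, 5 of 19 members rose and 4 fell. Gata3, a transcription factor gene of the nephric duct, rose 1.73-fold from 9.64 ± 0.304 to 16.7 ± 1.37, while the epithelial cadherin gene Cdh1 fell 1.87-fold (list adjusted p = 0.640). Of 8 podocyte genes, 3 fell, Wt1 among them, and 2 rose (adjusted p = 0.474). Of 22 erythroid genes, 2 rose and 2 fell, against 2 and 6 under quantile and cyclic loess normalization (adjusted p = 0.640), and of 18 macrophage genes 5 rose and 2 fell, with Aif1 1.39-fold higher and Coro1a 1.43-fold lower (adjusted p = 0.745). Genes of hepatocytes and gut endoderm went apart, with 3 of 14 higher and 4 lower (adjusted p = 0.597). Rbp4, the retinol carrier, rose 3.35-fold beside Ttr, while Spink1, a trypsin inhibitor gene, fell 4.75-fold and the imprinted gene Dlk1 2.32-fold. Of 12 retinoic acid genes, 6 rose and 2 fell (adjusted p = 0.640), and the list's median was 0.34 while its mean, with Aldh1a1 among the members, was -0.02. Crabp2, a retinoic acid binding protein gene, rose 1.54-fold and Aldh1a2, the main retinaldehyde dehydrogenase gene of the early embryo, 1.40-fold.

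Genes of proliferation, cell death and stress moved both ways. Of 33 cell cycle genes, 16 rose and 7 fell, with Mki67 1.64-fold higher and the mitotic kinase gene Plk1 2.07-fold lower. Under quantile normalization the counts were 11 and 10, and the list's adjusted p was 0.316. Of 22 genes of p53 and apoptosis, 6 rose and 6 fell (adjusted p = 0.640), with Pmaip1, which encodes the death activator NOXA, 1.87-fold higher and the p53 target Cdkn1a 1.70-fold lower. The median of that list was 0.01 and its mean -0.06. Of 22 immediate early and stress genes, 5 rose and 6 fell, with Jun 1.42-fold higher and the growth arrest gene Gadd45b 1.83-fold lower. That list's median was 0.02 although its test pointed down (adjusted p = 0.640). Of 28 genes of hypoxia and glycolysis, 10 rose and 6 fell, against 6 and 8 under quantile normalization (adjusted p = 0.640). Bnip3, a mitophagy gene induced by hypoxia, rose 2.48-fold, and Adm, which encodes adrenomedullin, fell 3.11-fold. Of 13 housekeeping genes, 6 rose and 5 fell, against 2 and 6 under quantile and cyclic loess normalization (adjusted p = 0.745). Actb rose 2.07-fold (log2 change 1.05 ± 0.08, SE) and Eef1a1 fell 1.60-fold, and both passed in the same direction under the other normalizations, where the log2 change of Actb was 0.59 (quantile) and 0.62 (cyclic loess) and that of Eef1a1, -0.68 in the main fit, was -1.08 and -1.04. A dimmer probe of Eef1a1 was 2.97-fold lower. Quantile normalization also took the log2 changes of Mki67, Crabp2 and Aldh1a2 from 0.71, 0.62 and 0.49 to 0.37, 0.35 and 0.28, all still past the threshold.

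Hox genes, which mark position along the body axis, showed 7 of 18 anterior members higher and 4 lower, and 3 of 10 posterior members higher and 1 lower (adjusted p = 0.745 and 0.438). Hoxb1 rose 2.89-fold, Hoxc9 1.85-fold and Hoxa5 1.61-fold (log2 change 0.69, and 0.38 under quantile normalization), while Hoxd9 fell 2.33-fold and Hoxa4 2.26-fold. Among 5 tested Y-linked genes, Kdm5d passed the threshold, 1.85-fold higher in the knockout at 8.58 ± 0.903 against 4.63 ± 0.181 (adjusted p = 1.45e-05). Eif2s3y had a log2 change of -0.34 ± 0.14 (SE, adjusted p = 0.0737), Uba1y -0.18 ± 0.10, Usp9y 0.16 ± 0.15 and Zfy1 0.61 ± 0.31, none of them past the threshold, and the list gave adjusted p = 0.745. For the lists of this and the preceding paragraphs that did not pass, the counts adjusted over the list alone differed by at most 1 gene in either direction.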

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

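Wt1 was lower under each alternative run, and leaving out 1 array gave log2 changes from -1.57 to -1.49 on the brighter probe and from -2.17 to -1.27 on the dimmer one. The 6221 calls became 4790 to 7317 with 1 array left out, and stayed within 1.5 times under each other alternative. With the replicate number as a block, there were 6019 calls, 709 of at least 2-fold and 13 lists, 5837, 690 and 13 of them shared with the fit without the block, so the replicate block changed no list call. The numbers share no more than a name: deviations of same-numbered arrays from their genotype means correlated at 0.00049, -0.021 and -0.0057 across probes, and no array correlated best with its own number. The 706 calls of at least 2-fold became 649 to 909 with 1 array left out and 371 among probes above the median probe, where fewer probes were tested. With a pseudocount at the 10th percentile they became 493, with 147 higher and 346 lower. Without any filter on dim probes 913 were called, with 428 higher and 485 lower. Quantile and cyclic loess normalization gave 185 and 175 higher and 545 and 549 lower, in place of 236 and 470. The 13 list calls became 7 to 13 with 1 array left out, 7 without knockout array 1, when the matrix, endothelial, muscle, sex determination, Wnt and BMP lists missed the threshold, and 0 with camera and an estimated correlation (5 at an unadjusted p under 0.05), while fry called 19. The cause was not tested. Of the named genes and list medians, none that passed the threshold reversed its direction under an alternative, and those that missed it after passing were 11 list results and 9 gene results over the processing alternatives that kept the camera test at its preset correlation, and 9 and 20 with 1 array left out. Of the named genes, 2 gained a call, Eif2s3y without a trend in the variance prior and Zfy1 without knockout array 3. Camera with an estimated correlation, counted apart, called none of these 13 lists. The deposited table carries no measure of background, so dim genes, among them those given as lower bounds, are limited by an unknown detection limit.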

Other observations

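The tests below of normalization, of gonadal primordium loss as the cause of the fall of Amhr2 and of Kdm5d, and the comparisons of the muscle and neural crest lists with the endothelial list without already seen genes, were chosen only after the results were seen, and the 4 added gene lists were written after the strongest genes had been looked at. Of the hormone genes of the pancreas and gut, Gip at 0.95 ± 0.28 (log2, SE, adjusted p = 0.0157) and the somatostatin gene Sst at 2.03 ± 0.14 (adjusted p = 9.46e-07) were higher beside Gcg and Pyy, 1 was lower, the cholecystokinin gene Cck at -0.63 ± 0.07 (adjusted p = 2.37e-05), and the insulin gene Ins2, whose signal lay near the limit for dim probes, did not pass (adjusted p = 0.873). Gip was dim too, with mean intensities of 0.284 in wild type and 0.545 in knockout against that limit of 0.217. Of the homeobox genes of stomach, gut and spleen mesenchyme, Barx1 at 2.49 ± 0.08 (adjusted p = 2.73e-09), Isl1 at 0.91 ± 0.09 (adjusted p = 1.05e-05) and Nkx3-2 at 0.50 ± 0.16 (adjusted p = 0.0303) were higher beside Tlx1 and Nkx2-5, 1 was lower, Hlx at -0.47 ± 0.09 (adjusted p = 0.000991), and Nkx2-3 stood at 0.19 ± 0.09 (adjusted p = 0.111). The largest falls of that list lay outside its homeobox genes, in Actg2 at -0.82 ± 0.08 (adjusted p = 1.72e-05) and Nfib at -0.75 ± 0.11 (adjusted p = 0.000174). Its members Foxf2 at 0.30 ± 0.09 (adjusted p = 0.0162) and Tcf21 at 0.38 ± 0.07 (adjusted p = 0.000843) were higher. Among neural genes, the transcription factor genes Nhlh2 (at least 3.91-fold, its wild-type signal lying below the limit for dim probes) and Myt1 (1.82 ± 0.09) and the radial glia gene Fabp7 (1.43 ± 0.08) were higher, while the receptor gene Gfra3 was lower at -0.60 ± 0.11 (adjusted p = 0.000911), and Zic2 stood at -0.14 ± 0.10 and Nes at -0.04 ± 0.08. Among somite genes, En1 at 1.61 ± 0.21, Tcf15 at 1.03 ± 0.07 and Pax9, at least 2.51-fold for the same reason, were higher, while Pax3 stood at -0.12 ± 0.07. The myogenic gene Myod1 had a log2 change of 1.60 ± 0.16. These genes were chosen after their values were seen. Of the list genes not looked at before, 4 of 11 gut and spleen mesenchyme genes were higher and 3 lower, 5 of 13 somite and sclerotome genes were higher and none lower, and 4 of 12 neural tube genes and 4 of 12 pancreatic and enteroendocrine genes were higher and 1 lower each, with 7 not past the threshold in either list.

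The first pattern is the higher muscle, neural, pancreatic and somite genes in knockout tissue. Lost gonadal and coelomic cells that raise all other types alike were 1 explanation examined. No gene of the neural crest list was among the strongest ones looked at. Its median lay 0.98 above that of the endothelial list (log2, 95% bootstrap interval over genes 0.54 to 1.41). These 2 lists thus did not move alike, but their opposite directions were known when they were paired. The endothelial list, which fell, may also not stand for all other types, so the comparison does not decide. The muscle list leaves this explanation open too. Its median lay 1.40 above that of the endothelial list (0.14 to 2.04) with such genes. An interval away from 0 had been written before that test as the outcome against the explanation. Without such genes the median lay 0.51 above, where the interval of 0.00012 to 1.62 ends at 0 to 2 decimals. That removal took out the list's 4 strongest gains and so lowered its median, while the first interval rests in part on them. As to normalization, 100% of the 29 probes at least 4-fold higher passed under both other normalizations, with log2 changes of at least 1.98. That outcome was nearly fixed, since these probes were picked for their size. Quantile normalization moved the median change of the brightest eighth only from 0.26 to -0.00024. The result shows only that the choice among these scalings does not remove the largest gains. Of the 236 probes at least 2-fold higher, 89.8% passed under both, which leaves normalization open for some of them. Neighbouring tissue carried along in the dissection of the knockout pool could not be settled: of the list genes not looked at before, 41.7% of 12 muscle genes, 33.3% of 12 pancreatic and enteroendocrine genes and 33.3% of 12 neural tube genes were higher, against 25.2% of all other tested genes. Their medians were 0.33 (95% bootstrap interval -0.14 to 1.32), 0.35 (-0.02 to 0.63) and 0.15 (-0.10 to 0.84). The members left out of these lists were all higher, so the shares and medians lie below those of the full lists. A difference in the makeup or identity of the ridge between the genotypes stays open and untested.

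A second pattern is the unequal loss of gonadal genes. Whether loss of the gonadal primordium's cells could be the whole cause of the 64.1-fold fall of Amhr2 is left open. The other members of the list had a median of -0.23 (log2, 95% bootstrap interval -0.81 to 0.08, 16 genes), but they went both ways and several are also expressed outside the gonad, so the limit of -1 written for that median did not follow from a loss of cells and the median does not decide. Nr5a1, the steroidogenic factor gene, had a log2 change of -0.40 ± 0.09 (SE) and Gata4 of -0.06 ± 0.09, and these genes were chosen after their values were seen. A dependence of single genes on Wt1 was not tested.

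The last pattern is Kdm5d, which was 1.85-fold higher in the knockout although each pool was labelled with 4 female and 1 male embryos. More male tissue as the whole cause would raise the other Y-linked genes by about as much, and the mean change of the other 4 tested minus that of Kdm5d was -0.82 (log2, 95% t interval over genes -1.55 to -0.09), but without knockout array 3 the interval reached 0.19, so a male excess, whole or partial, stays open. Eif2s3y stood at -0.34 ± 0.14, Uba1y at -0.18 ± 0.10, Usp9y at 0.16 ± 0.15 and Zfy1 at 0.61 ± 0.31 (SE), and none of them passed the threshold in the main fit. Under the alternatives, Eif2s3y passed as lower without a trend in the variance prior (adjusted p = 0.0300), which goes against a male excess, and Zfy1 passed as higher without knockout array 3 (0.96 ± 0.25, adjusted p = 0.0121), which goes with it. Whether these probes also detect X-linked relatives, which would shrink their changes, and other explanations for the single Kdm5d probe were not tested.

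The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. For each count, 1 of the 10 splits, the real one, reached the real value of 6221 probes, 706 of at least 2-fold and 13 lists. The highest of the other 9 splits gave 0, 0 and 5 (limma and camera), with at most 445 probes at an unadjusted p under 0.05. Each of these 9 splits put arrays of both genotypes in both groups, so the difference between genotypes widened the spread within groups. Their low probe counts were thus largely fixed in advance and do not show what arrays without a genotype difference would give.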
